A study of Homo sapiens with 8 samples.

How the data were processed

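Genomic DNA recovered by ChIRP with antisense probes against α-satellite RNA was sequenced from asynchronous and mitotic RPE1 cells. The labels list 8 libraries: for each condition 1 input, 1 labelled Scr, and the Odd and Even probe libraries. Groups were taken from the sample titles, and the Odd and Even libraries of a condition formed 1 group of 2 libraries. Input, Scr and separate Odd and Even values were not analysed here. The submitters' processing notes name fastp, Bowtie2 and MACS2 and the genome build hs1. They state no versions, and the settings and the control library used for peak calling are not given in the sources used here.

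Each condition was represented by 1 deposited peak list, called on the merged Odd and Even libraries per the labels. The lists have no header, so column meanings were read from the values and the order of the MACS2 broad peak table. The authors' pileup signal per peak is in an unstated scaling and served only to describe the lists. The authors' fold enrichment, a ratio of pileup to local background, and the deposited −log10 q value were used to rank and filter peaks within a list. A shared limit, a fold enrichment of at least 6 and a −log10 q of at least 5, was also applied to both lists. A further deposited score per peak, which never falls below 0.3, and 2 more unnamed columns, with lowest values of 1.00 and 1.50 in both lists, point to a filter by the authors. The rule of that filter is not stated. All listed columns were assigned to a group. Peak names carry running numbers that follow genome order in both lists, with a highest number of 75623 in the asynchronous and 150026 in the mitotic list. The listed peaks make up 42.4% and 22.4% of these numbers, so missing numbers were counted as calls removed before deposit. Peak starts sat on a grid: 97.4% of asynchronous and 97.8% of mitotic starts fell 0 to 5 bp past a multiple of 25 bp, where 24% would by chance. Positions are therefore resolved to about 25 bp. Reads in α-satellite arrays can map to many near-identical copies, and how such reads were placed is not given in the sources used here. Coverage of any array therefore depends on that choice.

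Peaks of both lists were joined into regions where gaps were at most 100 kb, and regions of at least 20 peaks were called dense. The largest region of a chromosome was the one with the most covered base pairs over both lists. Overlap required 1 bp, and the Jaccard index was shared over combined base pairs. Mitotic peaks were moved at random 100 times, within the chromosome up to the furthest listed peak or within their dense region, to give the level without association. These moves describe placement and not the spread between cultures. Shares carry Clopper-Pearson intervals, and ratios of counts carry exact conditional binomial intervals, both at 95%. For spacing, distances between starts up to 20 kb were counted, a moving mean was removed, and periods from 300 to 4000 bp in steps of 2 bp were scored with a cosine. The score was set against 100 sets whose starts were jittered by up to 1000 bp, and a period passed where it exceeded all of them in both lists, with a tolerance of 6 bp between lists. In the asynchronous list the limit was the highest jittered score at any period. In the mitotic list it was the highest within 6 bp of the asynchronous period, which is easier to pass. Peak ends and midpoints were scored likewise, also against 100 jittered sets. The most frequent distance was taken below 5000 bp in a window of 51 bp.

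Tested on simulated data, the overlap code returned 60% for a planted 60%, the region code found 5 of 5 planted regions, and the spacing code found 25 of 25 planted periods, either the period or a whole fraction of it, and 0 in 20 regions without a period, each against 20 jittered sets. The simulated regions without a period had starts drawn at random, with no 25 bp grid and no least distance between starts. Their rate of false calls may therefore not carry over to the lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

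The overlap, the counts and the spread over chromosomes were fixed before the data were examined, along with their alternatives. The dense regions, the outside peaks, the spacing, the grid and all tests on them were chosen afterwards. Peaks per Mb had been planned, but no chromosome lengths of build hs1 were used here, and shares of each list are given in their place. The planned work on repeat and gene annotation, the fixed gene lists and cell type markers, genes found in a single condition, and base composition was not run, because the gene table at hand is of assembly GRCh38.p14. On 9 chromosomes the furthest peak lies beyond the last gene of that table. The rule for named genes (those under the strongest peaks, with most covered length in a single condition, with the highest covered share in both, or in 3 centromere and scaffold lists) was therefore not applied, and no gene is named.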

Results

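The study mapped genomic DNA recovered with probes against α-satellite RNA, the transcripts of the tandem repeats that form human centromeres. The method was ChIRP-seq, in which biotinylated antisense probes pull an RNA and the chromatin bound to it out of sonicated cells, and the recovered DNA is sequenced. RPE1 cells, an immortalised line of human retinal pigment epithelium, were taken as an asynchronous culture and as mitotic cells. The labels list 8 libraries in 6 groups. Each condition had 1 input library, 1 library labelled Scr and 2 libraries pulled down with separate α-satellite probe sets, labelled Odd and Even. The deposited results analysed here were 1 peak list per condition, made from the merged Odd and Even libraries. With 1 list per condition there was no replicate error, so no difference between conditions was tested, and the intervals given with shares and ratios of peaks are exact 95% intervals that cover counting error only. Ranges given with randomly moved peaks are the lowest and highest of the sets drawn. Sequencing depth per library is not known from these lists.

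The first comparison asked where on the genome the DNA recovered with the α-satellite probes came from in each condition. Antisense probes can also pair with α-satellite DNA itself, and without the input and Scr libraries, not analysed here, DNA held by RNA was not separated from DNA bound by the probes. In both conditions nearly all of the listed peaks lay in a limited number of dense regions. The asynchronous list held 32035 peaks covering 47.5 Mb, and the mitotic list held 33553 peaks covering 48.1 Mb. Peaks lay on 23 chromosomes, the autosomes and X. When peaks of both lists less than 100 kb apart were joined and groups of at least 20 peaks were kept, 65 dense regions spanning 82.3 Mb held 99.2% of asynchronous peaks (99.1 to 99.3%) and 96.0% of mitotic peaks (95.8 to 96.2%). The largest region of each chromosome alone held 91.2% of the covered length of the asynchronous list and 89.5% of that of the mitotic list. On chromosome 3 the largest region held less than the others together, with 847869 bp in the asynchronous list against 564469 and 545454 bp. These shares describe the lists after the authors' filter. By the running numbers in the peak names, 20463 of 75623 asynchronous and 94621 of 150026 mitotic calls lay outside the dense regions before it, and it kept 57.6% and 58.1% of the calls inside against 1.26% and 1.42% outside. Dense regions were defined by listed peaks, so a higher kept share inside them is partly built in. This definition of a dense region was chosen after the peak positions had been seen. No annotation of the same genome build was used, so the regions are given by position and not by repeat class.

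The largest regions differed widely in how completely they were covered. All positions are on build hs1. The region on chromosome 3 (91711151 to 92595749) was covered over 95.8% of its length in the asynchronous list and 95.3% in the mitotic list, and that on chromosome 21 (10962530 to 11341447) over 94.7% and 95.7%. The region on chromosome 9 (44938730 to 47606780) reached 87.7% and 89.2%, and that on chromosome 8 (44183554 to 46370370) 84.9% and 85.2%. At the other end, the region on chromosome 10 (39391103 to 42061319) was covered over 33.4% and 31.9%, and that on chromosome 19 (24361877 to 30125272) over 40.2% and 38.1%. The median over the 23 regions was 70.7% in asynchronous and 72.9% in mitotic cells. These shares depend on where the 100 kb rule, applied to the same peaks, set the edges of a region. The neighbouring dense region on chromosome 3, from 90340404 to 91480644, was covered over 49.5% and 57.7%. Coverage with another gap was not computed. The authors' fold enrichment per peak, used here within each list, was also uneven. In the asynchronous list its median was 12.6 in the chromosome 3 region and 6.05 in the largest region of chromosome 7 (60410501 to 63850245).

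**Figure D1:**
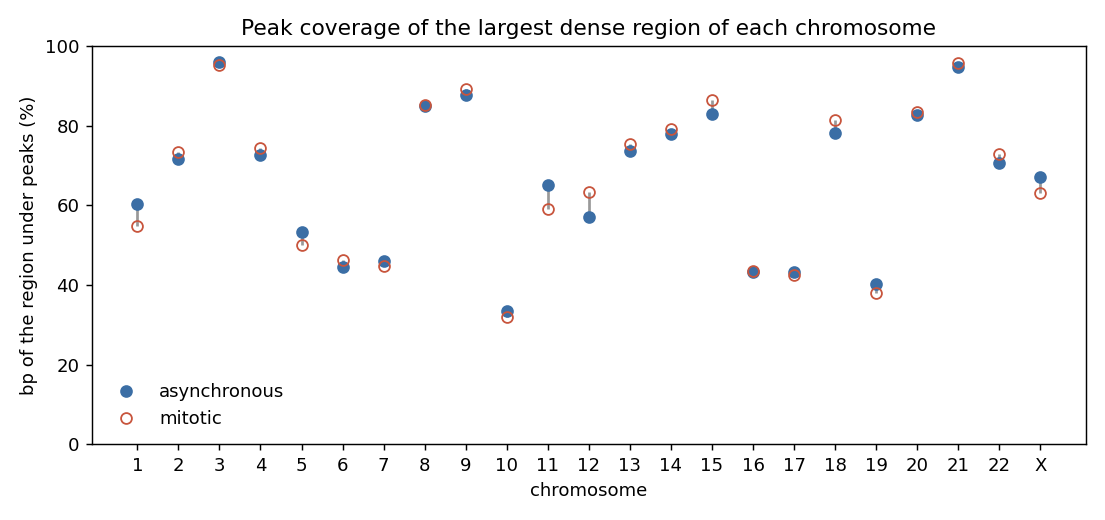
Percent of base pairs under peaks (vertical axis) in the largest dense region of each chromosome (horizontal axis), with filled circles for the asynchronous list, open circles for the mitotic list and a line joining the pair. Coverage ran from 33.4% on chromosome 10 to 95.8% on chromosome 3 in the asynchronous list, and the mitotic values lay close to the asynchronous ones.

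Peaks were spread unevenly over chromosomes. Chromosome 18 carried the largest share of covered length, 9.20% of the asynchronous and 9.44% of the mitotic list, in a region from 15542879 to 21125721. Chromosome 1 carried the most peaks, 7.85% of the asynchronous list and 8.72% of the mitotic list, but fewer among strong peaks: in the 25% of peaks with the highest fold enrichment its shares were 4.68% and 2.42%, so that the mitotic share was then the lower. Chromosome 21 carried the fewest, with 215 asynchronous and 197 mitotic peaks. The mitotic list had more peaks on 14 chromosomes and fewer on 9. The ratio of mitotic to asynchronous peaks was highest on chromosome 4, at 1.25 (1.14 to 1.37), followed by chromosome 16 at 1.23 (1.11 to 1.37) and X at 1.19 (1.11 to 1.28). It was lowest on chromosome 21, at 0.916 (0.751 to 1.12), and chromosome 20, at 0.920 (0.854 to 0.991). These intervals treat neighbouring peaks as independent, were not adjusted for 23 chromosomes and are not tests between conditions. Covered length often went the other way: all 9 chromosomes with fewer mitotic peaks had more of it in the mitotic list, and 7 of the 14 with more peaks had less. It went from 2.93 to 2.99 Mb on chromosome 20 and from 2.30 to 2.17 Mb on X.

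The second comparison asked how far the regions recovered in mitosis matched those of asynchronous cells. Most of the length covered by the filtered lists was shared, 81.4% of the asynchronous and 80.4% of the mitotic covered length. At an overlap of at least 1 bp, 26233 asynchronous peaks (81.9%, 81.5 to 82.3%) met a mitotic peak, and 26560 mitotic peaks (79.2%, 78.7 to 79.6%) met an asynchronous one. The lists shared 38.7 Mb, a Jaccard index of covered base pairs of 67.9%. When mitotic peaks were moved at random within their chromosomes 100 times, 4.33% of asynchronous peaks were met on average (3.87 to 4.71%) and the Jaccard index averaged 1.16%. Most of this overlap was also met when peaks stayed in their own region. Moving mitotic peaks only within their own dense region still left 77.9% of the asynchronous peaks in those regions met, against 82.4% observed. The Jaccard index separated the cases more clearly, at 68.5% observed against 48.4% after such moves (48.0 to 48.9%). Requiring a reciprocal overlap of at least 50% lowered the shared portion to 53.8% of asynchronous and 51.3% of mitotic peaks.

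With all peaks counted, covered length in the largest regions was nearly the same in both conditions. It summed to 43.3 Mb in asynchronous and 43.1 Mb in mitotic cells, a ratio of 0.995, with 14 regions higher and 9 lower in the mitotic list. With only peaks of a fold enrichment of at least 6 and a −log10 q of at least 5, 18 were higher and 5 lower. With all peaks the log2 ratio per region ranged from -0.14 to 0.15. The lowest value belonged to chromosome 1 (121618803 to 126846321), where coverage went from 60.4% to 54.7% while the number of peaks went from 2497 to 2753. Chromosome 11 (50605500 to 54488521) went from 65.2% to 59.2%, and X (57692455 to 61117620) from 67.2% to 63.2%, also with more peaks. Coverage of the chromosome 12 region (34285578 to 37371921) went the other way, from 57.0% to 63.2%. The Jaccard index per region lay between 37.9% on chromosome 16 and 96.5% on chromosome 3. This index rises with coverage by itself, and coverage was 43.2% and 43.4% in the first region against 95.8% and 95.3% in the second. No level after random moves was computed per region, so a difference in placement was not separated from coverage.

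The 42 smaller dense regions held more covered length in the mitotic list, 4.53 Mb against 3.98 Mb. Covered length was higher in 36 of them and lower in 6, with a median log2 ratio of 0.33 and a range from -0.47 to 1.10. Of these regions, 24 lay on chromosomes 13, 14, 15, 21 and 22, the acrocentric chromosomes, whose short arms carry the ribosomal RNA genes and satellite DNA. Their summed coverage was 15.7% in the asynchronous and 20.7% in the mitotic list, a ratio of covered length of 1.32, although they held 1377 peaks in the asynchronous list and 1269 in the mitotic list. Covered length was higher in 22 of the 24. The region on chromosome 15 from 14676154 to 14748649 went from 13775 to 29526 bp and that on chromosome 22 from 8492626 to 8823597 went from 13960 to 29456 bp. The 18 smaller regions on other chromosomes had a ratio of 1.08, with 14 higher in the mitotic list. Their median log2 ratio was 0.08, against 0.37 on the acrocentric chromosomes. Among these, the region on chromosome 7 from 60044377 to 60242547 went from 21222 to 42884 bp.

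The third comparison concerned peaks away from the dense regions, and was added after the lists had been seen. Peaks outside the dense regions were several times more frequent in mitotic cells, and they were short and weak. There were 258 in the asynchronous list (0.805%, 0.710 to 0.909%) and 1345 in the mitotic list (4.01%, 3.80 to 4.22%), a ratio of 5.21 (4.56 to 5.98). The size of the ratio depended on the definition of a dense region and was 3.21 (2.89 to 3.56) when at least 50 peaks were required. The mitotic count was higher on all 23 chromosomes, from 1.53 times (0.827 to 2.88) on chromosome 14 to 12.7 times (4.02 to 64.1) on chromosome 19. The interval on chromosome 14 included 1. The excess lay far from the dense regions: within 2 Mb of one the counts were 84 and 112, a ratio of 1.33 (0.996 to 1.79), and beyond 2 Mb they were 174 and 1233, a ratio of 7.09 (6.04 to 8.35). In the 10 Mb that follow the largest region of chromosome 1, where the pericentromeric heterochromatin of the long arm lies, there were 1 asynchronous and 28 mitotic peaks. The same window held 0 and 1 peaks on chromosome 9, and 31 and 19 on chromosome 16, where 26 and 15 belong to a smaller dense region. Median width outside the dense regions was 227 bp in the asynchronous and 219 bp in the mitotic list, and the median fold enrichment was 4.19 and 3.93, against 7.76 and 8.11 inside. The excess was not resolved among strong peaks: with a fold enrichment of at least 6 and a −log10 q of at least 5 there were 42 asynchronous and 58 mitotic peaks, a ratio of 1.38 (0.912 to 2.11).

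**Figure D2:**
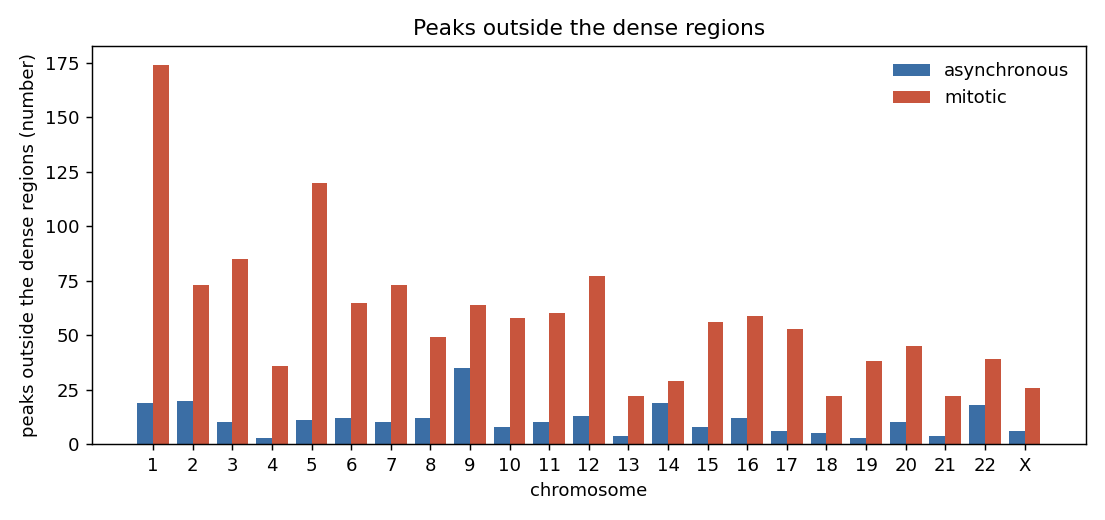
Number of peaks outside the dense regions (vertical axis) on each chromosome (horizontal axis), with blue bars for the asynchronous and red bars for the mitotic list. The mitotic bar is the taller on all 23 chromosomes, and the tallest is that of chromosome 1, with 174 mitotic peaks against 19 asynchronous ones.

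Most outside peaks were not shared. Of the asynchronous ones 52 (20.2%, 15.4 to 25.6%) met an outside peak of the mitotic list, and of the mitotic ones 46 (3.42%, 2.51 to 4.54%) met an asynchronous one. After random moves within chromosomes 0.0659% of the asynchronous ones were met on average, with a highest value of 1.16%. Sharing was more common near the dense regions, at 46.4% of asynchronous peaks within 2 Mb against 7.47% beyond. A few outside sites were strong in both lists. On chromosome 2, a cluster from 95000702 to 95070896 covered 16850 bp in asynchronous and 47481 bp in mitotic cells, with a highest fold enrichment of 13.2 and 13.4. A second cluster on chromosome 2, from 132644079 to 132683123, lay 37955 kb from the nearest dense region, covered 12105 and 20231 bp, and reached a fold enrichment of 9.05 and 12.9. It lies on the long arm, which carries the remnant of an ancestral centromere, and whether the cluster falls in that remnant was not tested. On chromosome 3, from 92869528 to 92903098, the lists covered 33288 and 33546 bp. On chromosome 9, single mitotic peaks of 6350 and 6196 bp lay at the sites from 77598776 to 77605304 and from 79941054 to 79947444, where 5891 and 6001 bp were covered in asynchronous cells. Other strong clusters covered less in mitotic cells: on chromosome 9 from 42722905 to 42757847, 19483 bp in asynchronous and 10771 bp in mitotic cells, and on chromosome 16 from 39503328 to 39545556, 8783 and 6197 bp. These sites were picked after their values had been seen.

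The last description, also added after the lists had been seen, concerned the order of peaks inside the largest regions. α-Satellite DNA is built from monomers of about 170 bp arranged in chromosome-specific higher-order repeats. Peak starts recurred at regular distances in 11 of the 21 largest regions with at least 200 starts per list. In each of these 11, the leading period of the asynchronous list scored above all 100 sets with jittered starts, and the same period did so in the mitotic list. Both lists lie on the same reference sequence, so recurrence in the mitotic list is not independent support. Spacing set by that sequence or by read placement was not separated from spacing of the bound RNA. The mitotic list's own leading period was another in 4 of the 11: 1024 bp on chromosome 7, 1280 on 15, 1018 on 18 and 684 on X. Those on chromosomes 7, 15 and 18 lie near a whole multiple of the asynchronous period given below, and that on X does not. The clearest case was chromosome 14 (10067329 to 12783724), with a period of 1366 bp and a score of 31.0 in the asynchronous and 34.9 in the mitotic list, against 5.72 and 4.05 for the highest jittered sets. The mitotic limit was taken only within 6 bp of the asynchronous period, so these limits are not alike. Chromosome 17 (23411454 to 27656948) had a period of 1354 bp with scores of 23.5 and 21.4, chromosome 18 one of 510 bp with 18.6 and 18.8, and chromosome 6 one of 434 bp with 18.6 and 28.1. The other periods were 340 bp on chromosome 5, 512 on 7, 848 on 11, 608 on 13, 636 on 15, 682 on 20 and 1028 on X. Of the 11 periods, 8 lay within 10 bp of a multiple of 170 bp, as 13.1% of the periods scanned do (exact one-sided binomial p = 9.73e-06). That p treats the arrays as independent, and the tolerance was set after the periods were seen. The scored period can be a whole fraction of the distance at which peaks recur: the most frequent distance between asynchronous starts was 3051 bp on chromosome 6, 2673 bp on 17 and 2725 bp on 14, and it exceeded the period by more than 1.5 times in all 11 regions. No period of peak starts passed in both lists in the other 10 regions. The calls and periods depended on the positions used. From peak ends 15 regions passed against 100 jittered sets, including those of chromosomes 10 and 19 (both 340 bp), and the period became 510 bp on chromosome 6, 386 on 13, 1290 on 15, 2728 on 17, 1018 on 18 and 514 on X. From midpoints 6 passed, and the regions of chromosomes 5, 11, 13, 15, 20 and X no longer did. The period from midpoints became 1020 bp on chromosome 6, 1026 on 7 and 1356 on 14. Periods near a multiple of 170 bp made up 12 of the 15 from ends and 5 of the 6 from midpoints.

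**Figure D3:**
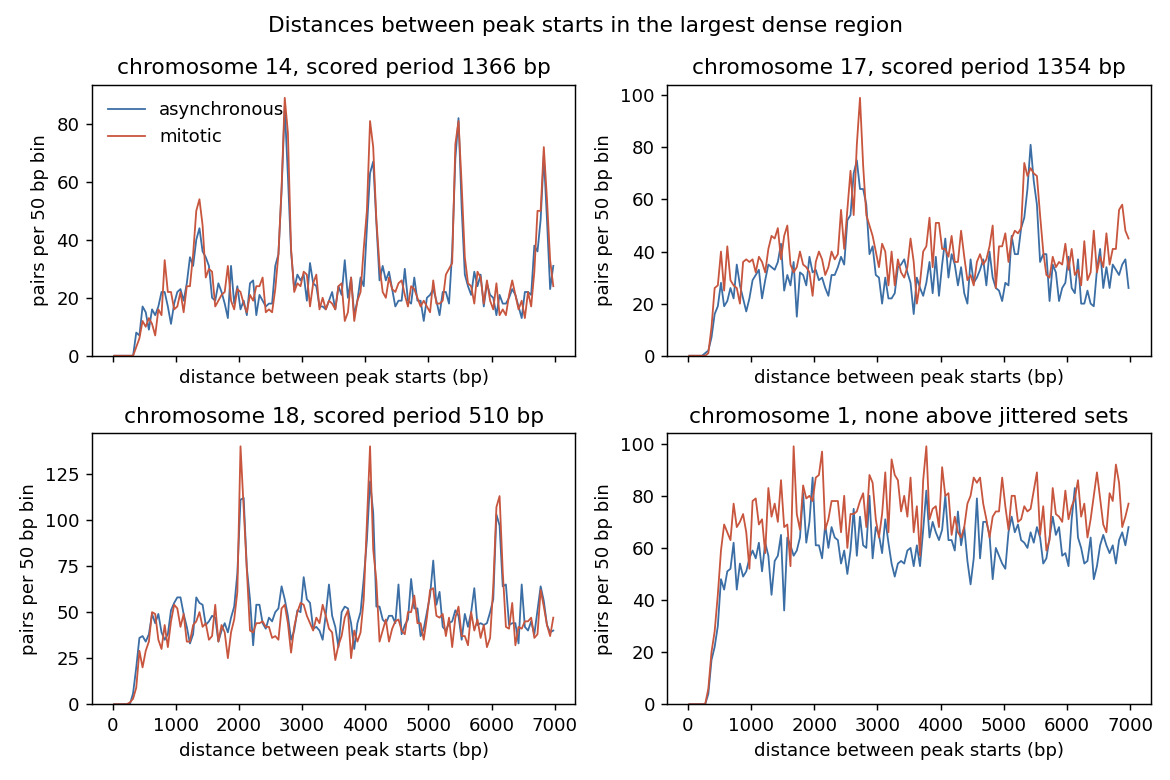
Number of pairs of peak starts per bin of 50 bp (vertical axes) against the distance between the starts in bp (horizontal axes) in the largest dense region of chromosomes 14, 17, 18 and 1, with the asynchronous list in blue and the mitotic list in red. Sharp maxima recur in both lists on chromosomes 14, 17 and 18, at 1 or several times the scored periods of 1366, 1354 and 510 bp, and no period of peak starts passed on chromosome 1.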

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

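The settings for outside peaks, dense regions and spacing, and the overlap inside and outside the dense regions, were chosen after the data had been seen; the others were fixed before. The ratio of outside peaks stayed above 1 throughout, but directions turned elsewhere: the order of the lists on chromosome 1, and the change of covered length in 8 of 65 dense regions under the shared limits, 8 of 55 in the upper 50%, 13 of 44 in the upper 25% and 4 of 65 after merging. Of 61 alternative values 19 stayed within the interval, or within 1.5 times, of the reported one, and 42 moved. No paired analysis was possible because each condition has 1 list of merged libraries. Leaving out α-satellite arrays, and every setting on genes, repeats and sequence, was not run, since no hs1 annotation was used here. Depth per library is unknown and limits all comparisons of weak peaks.

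Counts fell by construction. Keeping the upper 50% of each list by fold enrichment left 16018 asynchronous and 16777 mitotic peaks. The upper 25% left 8009 and 8389 peaks covering 20.5 and 22.2 Mb. Merging peaks within 1 kb left 8336 and 9490. For the moves that follow, the cause was not tested. The shared percentages of asynchronous and mitotic peaks were 76.8 and 74.7 with 50% of the peak covered, 53.8 and 51.3 with reciprocal overlap, 80.0 and 77.0 in the upper 50%, 68.9 and 65.1 in the upper 25%, 78.3 and 78.5 with equal numbers of top peaks, 78.7 and 70.4 after merging, 82.4 and 82.3 in the dense regions only, and 20.2 and 3.42 outside them. The Jaccard index was 58.4% in the upper 25%, 73.3% after merging and 16.4% outside the dense regions. Chromosome 1 held 6.84% and 5.12% of peaks in the upper 50%, 4.68% and 2.42% in the upper 25%, and 6.65% and 6.02% of covered length, so its mitotic share lay above the asynchronous one by peak number and below it in these 3 settings.

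The ratio of outside peaks was 6.63 with gaps of 500 kb, 6.17 with 10 and 3.21 with 50 peaks per dense region, and 7.09 beyond 2 Mb. Among stronger peaks it was 1.14 (0.610 to 2.16) in the upper 50%, 1.38 (0.504 to 3.94) in the upper 25%, from 8 and 11 peaks, and 1.38 under the shared limits, so no excess was resolved among strong peaks. Dense regions with more covered length in the mitotic list made up 76.9% of all, and 89.2% under the shared limits. The higher median fold enrichment of the mitotic list in these regions can favour it under those limits. Spacing was found in 15 regions from peak ends, in 6 from midpoints, with periods that moved, and in 12 with jitter in steps of 25 bp. The latter were the 11 reported and chromosome 22, which also passed from peak ends and midpoints but from starts is at the margin: its asynchronous score of 5.78 lay between the highest jittered scores of 5.53 with that jitter and 6.55 with the other, and which side it falls on can change with the random draw.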

Other observations

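All tests of the families and of the weak regions in this part were chosen after the result had been seen; the 3 tests on outside peaks were written down before their values were computed, but after the excess had been noticed.

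The running numbers in the peak names give a view of the calls before the authors' filter. Inside the dense regions the numbers spanned 55160 calls in the asynchronous and 55405 in the mitotic list, of which 57.6% and 58.1% were listed. Outside, they spanned 20463 and 94621 calls, of which 1.26% and 1.42% were listed. Calls inside were counted between the first and last listed peak of a region, so the contrast of inside with outside is partly built in. On chromosome 14, a cluster from 82792818 to 82823945, 70009 kb from the nearest dense region, held 1 asynchronous peak with a fold enrichment of 4.94 and 5 mitotic peaks reaching 9.94. On chromosome 9, the cluster from 44705500 to 44776294 covered 6277 bp in asynchronous and 27335 bp in mitotic cells.

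The excess of outside peaks in the mitotic list may come from more calls entering the filter. The ratio of the listed shares outside the dense regions, mitotic over asynchronous, was 1.127 (0.988 to 1.29), so the filter passed calls at about the same rate and the excess was already present before it. Without peaks at the top of the authors' per-peak score, 217 asynchronous and 1086 mitotic outside peaks were left. The ratio was then still 5.005 (4.32 to 5.82), so the excess did not rest on peaks at the top of that score. Short peaks that pass its floor of 0.3 at lower values were not removed. Whether very short peaks pass the score trivially therefore stays open. A looser effective threshold in the mitotic list stays open. Under shared stricter limits, with 42 and 58 peaks, the ratio was 1.381 (0.912 to 2.11). That interval lies below the 5.21 of all outside peaks and includes 1. A looser threshold and a gain of weak sites in mitosis would both lower the ratio under such limits, so the test cannot separate them. The median −log10 q of outside peaks was 3.72 in the asynchronous and 3.14 in the mitotic list, which either could give. Mitosis itself and a difference in depth or background between the libraries also stay open, untested, because each condition has a single list.

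The gain of covered length in the smaller dense regions may reflect weak regions being called more completely in the mitotic list wherever they lie. In the 10 regions off the acrocentric chromosomes with an asynchronous median fold enrichment under 6, the median log2 ratio was 0.3126, with an order-statistic interval from -0.25 to 0.86. Picking regions for a low asynchronous value favours a gain by itself, so this median carries little weight, and it was 0.20 in 8 regions picked on the mean of both lists (-0.47 to 1.01) and -0.25 in 3 picked on the mitotic list. On chromosomes 13, 14, 15, 21 and 22 the weak regions had a median of 0.40 in 18 regions picked on that mean (0.25 to 0.62) and 0.53 in 13 picked on the mitotic list (0.20 to 0.71). Whether the gain is specific to the acrocentric chromosomes was not resolved, and a change of their short arms in mitosis stays open, untested.

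A hypothesis is that the direction of change in the largest regions could follow the suprachromosomal family of the array, taken from general knowledge. Covered length was higher in mitotic cells in all 11 family 2 chromosomes (mean log2 ratio 0.03 ± 0.02 SD), in 3 of 8 of family 1 (-0.01 ± 0.08) and in 0 of 3 of family 3 (-0.08 ± 0.06), with chromosome 1, which holds arrays of families 1 and 3, left out. Of 4 contrasts run, family 2 against the rest gave a difference of 0.06 and a two-sided permutation p of 0.0257, and family 3 against the rest gave -0.10 and an exact permutation p of 0.0143, both 0.0514 after Benjamini-Hochberg adjustment, and none of the 4 fell below 0.05 after it; for family 2 the unadjusted p was 0.0128 with chromosome 1 among the rest and 0.125 with it in family 2. Family 2 regions were also more completely covered (79.8% against 53.5%). After removal of a linear trend on covered share a difference of 0.0329 was left, with a permutation p of 0.2241. The trend was fitted over all families, so its removal can also take out part of the family difference. Among the 11 chromosomes outside family 2 the correlation of change and covered share was r = -0.03 (permutation p = 0.990). Family and coverage therefore cannot be told apart with so few regions. The contrast depended on the peaks used. In the 4 other peak settings the unadjusted permutation p of family 2 against the rest lay between 0.113 and 0.658. The difference kept its sign in all 4. It was larger in the 2 settings that cut each list by rank of fold enrichment, at 0.185 and 0.351. It was smaller under the shared limits, at 0.0236, and after merging, at 0.0326. Under the shared limits covered length was higher in 11 of 11 chromosomes of family 2 and 6 of 8 of family 1. In family 3 it was higher in 1 of 3. The higher p does not argue against the hypothesis where the difference grew. The hypothesis still has little support, since none of these contrasts was resolved. Near-identical arrays are also not independent.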
